A study of Sus scrofa with 12 samples.

How the data were processed

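RNA came from the subcutaneous fat of the mid-back. The pigs were of the Guangdong small-eared breed (GS) or the Yorkshire breed (YK), and 9 d or 80 d old. The labels give 3 samples for each breed and age, 12 libraries in all, and the groups are written here YK_9d, GS_9d, YK_80d and GS_80d. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a stranded KAPA kit. The labels enter adipocyte as cell type, although the source is whole adipose tissue. The labels say only that the samples are separate samples, not that they came from separate animals or litters. The p-values therefore measure only the spread between these samples, which may be technical.

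The authors deposited 1 table of expected counts per gene, with 24358 pig Ensembl gene IDs and no scaling between libraries. The aligner, the counting tool and the annotation are not given in the sources used here. The submitters' processing notes name only the mouse build mm10, while every gene ID in the table is a pig ID, so no genome coordinates are printed. All values are whole numbers, and 5389 genes are at 0 in every library. Low values pile up at multiples of about 3.74: over the 12 libraries 3354 values equal 4, against 1233 that equal 3 and 795 that equal 5. A sequenced fragment thus adds about 3.74 units, and the values overstate the number of fragments by that factor. The unscaled totals ran from 45435480 to 60993349 units per library. The values were tested as deposited, and a test on the divided and rounded values was run as an alternative. Whether the counting used the strand of the reads is not given in the sources used here, so reads of overlapping genes and of antisense neighbours may not have been told apart.

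Symbols came from the supplied table of gene IDs, which names 14692 of the genes. IGF2 and MKI67, which were to be reported in every comparison, carry no symbol in that table and were not analysed here. Genes with enough counts by edgeR's filterByExpr were tested, 15425 in all, of which 12779 (82.8%) have a symbol. Libraries were scaled with TMM factors, which ran from 0.888 to 1.10. A negative binomial quasi-likelihood model with robust dispersions was fitted to all 12 libraries with the 4 groups as terms in edgeR 4.0.16 under R 4.3.3 (limma 3.58.1, statmod 1.5.0). It left 8 residual degrees of freedom, and the common dispersion was 0.267. The comparisons were GS minus YK at each age, 80 d minus 9 d in each breed, and the breed by age interaction, which is the difference between the age differences. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and the threshold was an adjusted p of 0.05. Standard errors (SE) of log2 fold changes were computed as the fold change divided by the square root of the F statistic. Levels are given as CPM with TMM scaling, as mean ± SD over 3 libraries unless another n is given.

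The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 8 largest increases and 8 largest decreases (5 and 5 for the interaction) among genes past the threshold with a symbol, a mean of at least 2 log2 CPM and groups that do not overlap. It added up to 4 members of each list with the smallest adjusted p, or the 2 most highly expressed members where none passed. A further 15 genes, among them LEP, ADIPOQ, PPARG, FASN, SCD and DLK1, were named whatever their result. RGS2, GATA2 and KDM5D are named outside this rule and were chosen after their values were seen.

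There were 42 gene lists for adipocyte function, lipid metabolism, growth, stress, immunity and other cell types that back fat can hold, and 40 had at least 5 tested members. These were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. Alternatives were camera with an estimated correlation, and fry, which asks whether the genes of a list move on balance one way, or change in either direction, and does not compare a list with other genes. The tissue was analysed in bulk, so marker lists describe transcripts and give no cell share. A group at 0 in all of its libraries was set to a floor of 3 fragments over the group, which covers counting error only, and folds against it are given as lower bounds.

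The procedure was tested on simulated data, with 200 genes changed by 2-fold or 4-fold in counts drawn with the dispersions of these libraries. At 4-fold, edgeR recovered 57.6% of the changed genes for the breed difference at 9 d, 60.6% at 80 d, 56.7% and 53.5% for age in YK and GS, and 19.2% for the interaction. At 2-fold it recovered 2.02%, 6.12%, 4.08%, 2.02% and 0% in the same order, with 3, 6, 1, 1 and 0 false calls. For the breed difference at 80 d, DESeq2 recovered 74 of 100 genes at 4-fold and 19 of 100 at 2-fold with 46 false calls, and limma-voom 55.6% and 7.14% with 7. A planted change of the lipogenesis list was found in each comparison and no other list was called. Each gene was drawn independently, so the simulation does not test the list calls against correlation between genes. Each gene also had the same dispersion in every group and, apart from the planted changes, the same mean level. The false calls therefore do not cover groups of unequal spread or single libraries with transcripts of other tissues, both of which these data hold.

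The alternatives were other scalings (DESeq2's size factors, upper quartile, library size only), other filters (none, or 1 CPM in 3 libraries), other tests (DESeq2 1.42.0, limma-voom with quality weights, a test against a 1.5-fold change), a replicate block, the 6 libraries of a comparison alone, and leaving out each library in turn. Chosen after seeing the data were fits without the 3 libraries that hold skeletal muscle transcripts, with a skeletal muscle score as a covariate, without the 2 YK_80d libraries with the most T cell transcripts, without the 2 YK_9d libraries with the most skin transcripts, and on the divided values. Other splits of the samples were refitted as a check of the counts. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. No library was left out of the reported fit.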

Results

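Gene expression in back fat was compared between GS, an indigenous breed of southern China, and YK, a commercial breed, at 9 d and at 80 d of age, with 3 libraries in each of the 4 groups. The labels describe the purpose as comparing the breeds at different ages. The deposited totals ran from 45435480 units in YK_80d replicate 1 to 60993349 in YK_9d replicate 1, and 1 sequenced fragment adds about 3.74 units. The 10 most abundant genes took 12.2% to 18.4% of each library, and mitochondrially encoded genes took 7.59% to 16.3%.

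Libraries of the same group correlated with Spearman coefficients of 0.926 to 0.980 across genes, and libraries of different groups with 0.907 to 0.955. The GS_80d libraries were the closest, at 0.976 to 0.980, against at most 0.964 for other pairs within a group. Their chi-square per degree of freedom was 35.6 to 47.8, against at least 86.0 for those pairs. The reported fit pools the spread of all 4 groups, so this closeness enters every comparison. With only the 6 libraries of a comparison, the genes past the threshold went from 409 to 1055 for age in GS. For breed at 80 d they went from 944 to 849. In the comparisons without GS_80d they went from 157 to 29 for breed at 9 d and from 186 to 46 for age in YK. Unequal spread and the smaller number of libraries were not tested apart. No pair within a group differed by as little as sampling noise, the lowest chi-square per degree of freedom being 35.6. The first principal component held 22.8% of the variance and the next 15.6%. Transcripts of other tissues were uneven between libraries. Skeletal muscle genes, such as those of the contractile apparatus, took 2.02% of the counts in YK_80d replicate 3, 1.86% in GS_9d replicate 3 and 0.425% in YK_9d replicate 1, against at most 0.0893% in the others. Skin genes stood highest in YK_9d, with a median of 1.58, 3.49 and 5.62 log2 units above their gene means in replicates 1, 2 and 3, against at most -0.17 in any other library. T and NK cell genes stood highest in YK_80d replicates 2 and 3, with medians of 2.22 and 2.78, against at most 0.57 elsewhere.

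**Figure D1:**
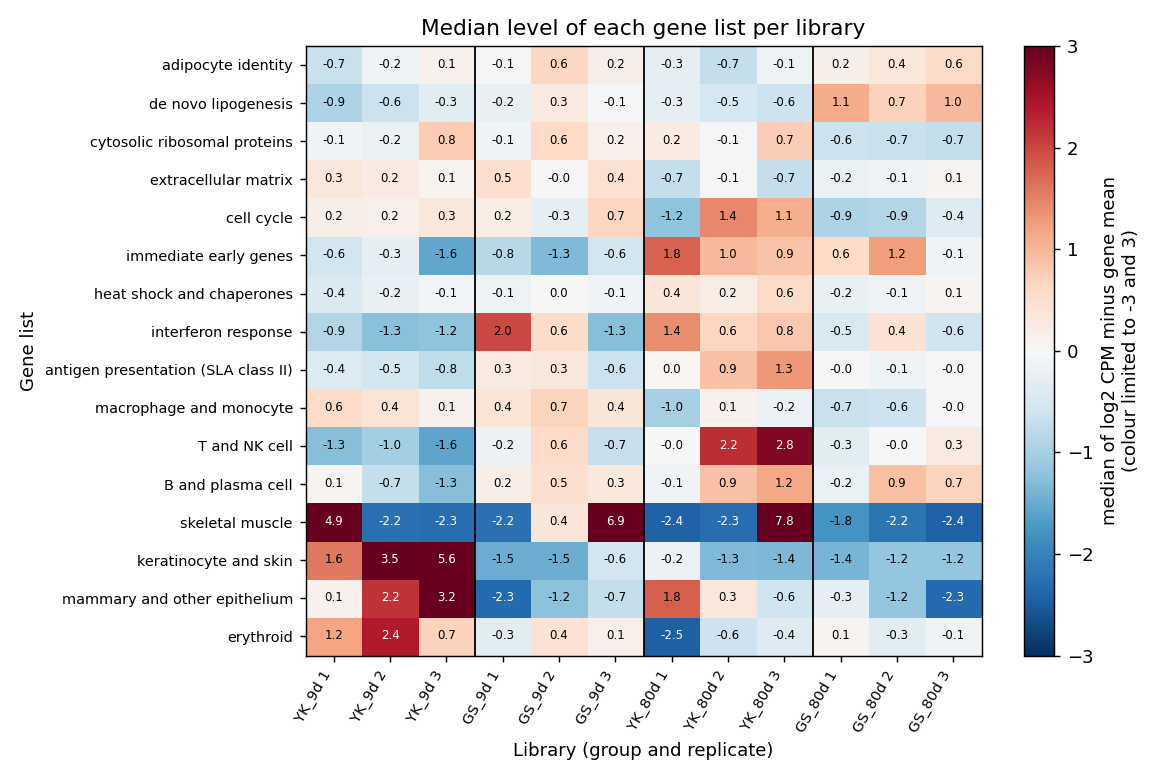
Median level of 16 gene lists in the 12 libraries, as log2 CPM minus each gene's mean, with the colour limited to -3 to 3. Skeletal muscle transcripts stood out in YK_80d replicate 3, GS_9d replicate 3 and YK_9d replicate 1, skin transcripts in YK_9d, and T and NK cell transcripts in YK_80d replicates 2 and 3.

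The breed difference at 9 d asks how the fat of the breeds differed in the first days of life. KIT, the receptor of stem cell factor, stood at 67.6 ± 8.66 CPM in YK and 8.46 ± 1.56 in GS, a log2 difference of -2.997 ± 0.34 (SE; adjusted p = 0.00748). LDHB, a subunit of lactate dehydrogenase, was higher in GS at 307 ± 79.3 against 25.6 ± 18.4 CPM (3.58 ± 0.44, adjusted p = 0.00748). TSHR, the thyrotropin receptor, was higher by 3.36 ± 0.42 (adjusted p = 0.00748), and PFKFB1, which makes and breaks down a regulator of glycolysis, by 3.57 ± 0.47 (adjusted p = 0.00938). CDC45, a replication factor, was lower in GS at 8.55 ± 2.91 against 295 ± 61.01 CPM (-5.11 ± 0.72, adjusted p = 0.0160), but its reads could not be checked against a genome, and the cell cycle list had a median of -0.06 (adjusted p = 0.960 with an estimated correlation; 1 of 42 genes higher when adjusted over the list alone). SLC6A4, the serotonin transporter, was lower by a log2 difference of -2.56 ± 0.42 (adjusted p = 0.0257). For each of these genes all 3 GS libraries lay on the same side of all 3 YK libraries. That held for all 157 genes that passed at 9 d, so it adds no support.

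Of 15425 genes tested, 157 passed the threshold at 9 d, 101 higher and 56 lower in GS, and 2220 had an unadjusted p under 0.05. The groups did not overlap for 18.5% of genes, against 10% by chance. The count was 5 without YK_9d replicate 2, 41 without YK_9d replicate 1, 284 without YK_9d replicate 3, 35 without GS_9d replicate 1 and 17 without GS_9d replicate 2. Of the 29 named genes past the threshold, KIT and PFKFB1 remained past it whichever library was left out. LDHB and TSHR each lost the call without YK_9d replicate 2 (both adjusted p = 0.0516). CDC45 lost it without YK_9d replicate 2, GS_9d replicate 1 or GS_9d replicate 2 (adjusted p up to 0.0850), and SLC6A4 without the same libraries (up to 0.102). Those calls were lost with log2 differences of 3.38 for LDHB, 3.21 for TSHR, -5.28 to -4.85 for CDC45 and -2.54 to -2.31 for SLC6A4.

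Few enzymes of fatty acid synthesis passed at 9 d, although 17 of the 21 genes of de novo lipogenesis had positive differences, with a median of 0.62. Of the 21 genes 3 were higher in GS, ACSS2 (1.12 ± 0.20, adjusted p = 0.0317), IDH1 (1.59 ± 0.30, 0.0347) and ELOVL5 (1.54 ± 0.31, 0.0449), and 5 were higher and 1 lower when adjusted over the list alone. FASN, fatty acid synthase, differed by 1.72 ± 0.53 (adjusted p = 0.146) and SCD, stearoyl-CoA desaturase, by 0.72 ± 0.74 (0.748). DGAT2, which makes triacylglycerol, was higher by 2.38 ± 0.49 (adjusted p = 0.0449), and so was CIDEC, a lipid droplet protein, by 1.81 ± 0.38 (0.0449). The lipogenesis list had an adjusted p of 0.000257 by the preset correlation and adjusted p = 0.545 with an estimated correlation. Its 3 calls became 0 without YK_9d replicate 1, YK_9d replicate 2 or GS_9d replicate 2 and 1 without GS_9d replicate 1 or 3, while 4 were higher and 1 lower without YK_9d replicate 3. DGAT2 and CIDEC lost their calls in 4 and 5 of the 6 fits that left out 1 library, with adjusted p up to 0.168 and 0.161.

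Some contractile genes of smooth muscle were lower in GS at 9 d. Of 17 list members, 8 with positive and 9 with negative differences (median -0.02), 3 passed, TAGLN (-1.66 ± 0.29, adjusted p = 0.0317), ACTA2 (-1.67 ± 0.34, 0.0449) and ACTG2 (-3.48 ± 0.71, 0.0450). Adjusted over the list alone, 5 were lower and 2 higher, and the list itself had adjusted p = 0.0640, and adjusted p = 0.545 with an estimated correlation. These 3 calls were 2 without YK_9d replicate 1, 1 without YK_9d replicate 3 and 0 without any other of the 6 libraries. They were 1 without the libraries with muscle transcripts. Over the 20 alternative runs the smallest log2 differences were -1.43 for TAGLN, -0.94 for ACTA2 and -1.33 for ACTG2. The keratinocyte and skin list had a median of -5.43, or -5.06 with the 5 members at 0 in a group set to the floor. Of its 18 members 1 passed, KRT71, a keratin of the hair follicle, which was at least 110-fold lower in GS_9d (all 3 libraries at 0) and lost its call in 5 of 6 fits without 1 library (adjusted p up to 0.168). Adjusted over the list alone, 13 were lower, with adjusted p = 0.545 with an estimated correlation. Of 31 interferon response genes 1 was higher in GS, USP18 (2.39 ± 0.49, adjusted p = 0.0450), and 20 were higher when adjusted over the list alone, with a median of 1.94 and adjusted p = 0.545 with an estimated correlation. The list stood at 1.99, 0.56 and -1.27 in GS_9d replicates 1, 2 and 3, against -0.88, -1.26 and -1.21 in YK_9d, so replicate 3 lay with YK. USP18 lost its call in 5 of 6 fits without 1 library (adjusted p up to 0.1896). Without YK_9d replicates 2 and 3, which hold the most skin transcripts, 11 genes passed in place of 157, and without the 3 libraries with muscle transcripts 39 passed.

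**Figure D2:**
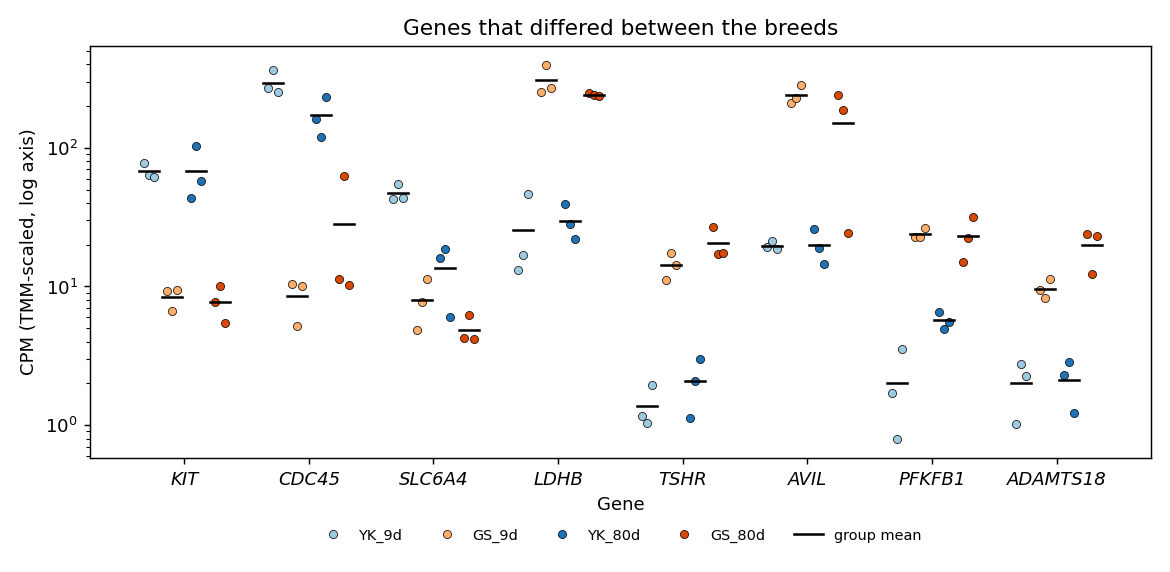
CPM of 8 genes in each library on a log axis, with bars at the group means. KIT averaged 67.6 and 67.7 CPM in YK at 9 d and 80 d, and 8.46 and 7.72 CPM in GS.

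At 80 d enzymes of fatty acid synthesis were higher in GS. SCD stood at 4023 ± 2375 CPM in GS and 38.6 ± 29.4 in YK, a fitted 104-fold difference (log2 6.70 ± 0.95, adjusted p = 0.00381). FASN stood at 5588 ± 3016 against 210 ± 122 CPM (4.74 ± 0.60, adjusted p = 0.00213), ACLY, which supplies cytosolic acetyl-CoA, at 389 ± 63.6 against 71.5 ± 13.5 CPM (2.44 ± 0.24, adjusted p = 0.000599), and ACACA, acetyl-CoA carboxylase, at 456 ± 39.9 against 59.1 ± 11.7 CPM (2.95 ± 0.42, adjusted p = 0.00305). ELOVL6, an elongase, was higher by 3.28 ± 0.56 (adjusted p = 0.00777). All 3 GS libraries lay above all 3 YK libraries for these genes, and all kept the call whichever library was left out. The groups did not overlap for 928 of the 944 genes that passed at 80 d, so the first point adds little. Of 21 lipogenesis genes 13 were higher and 1 lower in GS, and 16 were higher and 2 lower when adjusted over the list alone, with adjusted p = 5.27e-17 by the preset correlation and adjusted p = 0.153 with an estimated correlation. The 13 were 9 to 12 when 1 library was left out, 10 without the libraries with muscle transcripts, and 3 without YK_80d replicates 2 and 3, which hold the most T cell transcripts. In that fit, with a single YK_80d library left, the log2 differences were 6.98 ± 1.49 for SCD, 2.68 ± 0.69 for ACACA and 3.48 ± 0.98 for ELOVL6, which did not pass (adjusted p = 0.0598, 0.0866 and 0.113), since the SE grew while the differences stayed of similar size.

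Some triacylglycerol synthesis genes were higher as well. Of 13 members, 8 with positive differences (median 0.32), 3 were higher in GS_80d, also when adjusted over the list alone: AGPAT1 (1.88 ± 0.26, adjusted p = 0.00305), GPAM (2.498 ± 0.37, 0.00381) and DGAT2 (2.79 ± 0.50, 0.00868), with adjusted p = 0.602 with an estimated correlation for the list. Of 24 adipocyte identity genes 6 were higher, among them CIDEC (1.89 ± 0.38, adjusted p = 0.0151), CEBPA, a transcription factor of adipocytes (1.36 ± 0.30, 0.0244), and PLIN1, which coats lipid droplets (1.31 ± 0.32, 0.0346), and 8 were higher and 2 lower when adjusted over the list alone, with adjusted p = 0.602 with an estimated correlation. These 6 were 0 to 3 when 1 library was left out and 0 without the libraries with muscle transcripts. CIDEC lost the call without YK_80d replicate 3 or GS_80d replicate 3 (adjusted p = 0.0594 and 0.0553), CEBPA in 4 of 6 such fits and PLIN1 in 6 of 6 (up to 0.0677 and 0.105). PPARG, the master regulator of adipocytes, differed by 0.29 ± 0.27 (adjusted p = 0.564), ADIPOQ, adiponectin, by 0.90 ± 0.41 (0.207) and LEP, leptin, by 3.05 ± 0.91 (0.0778).

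**Figure D3:**
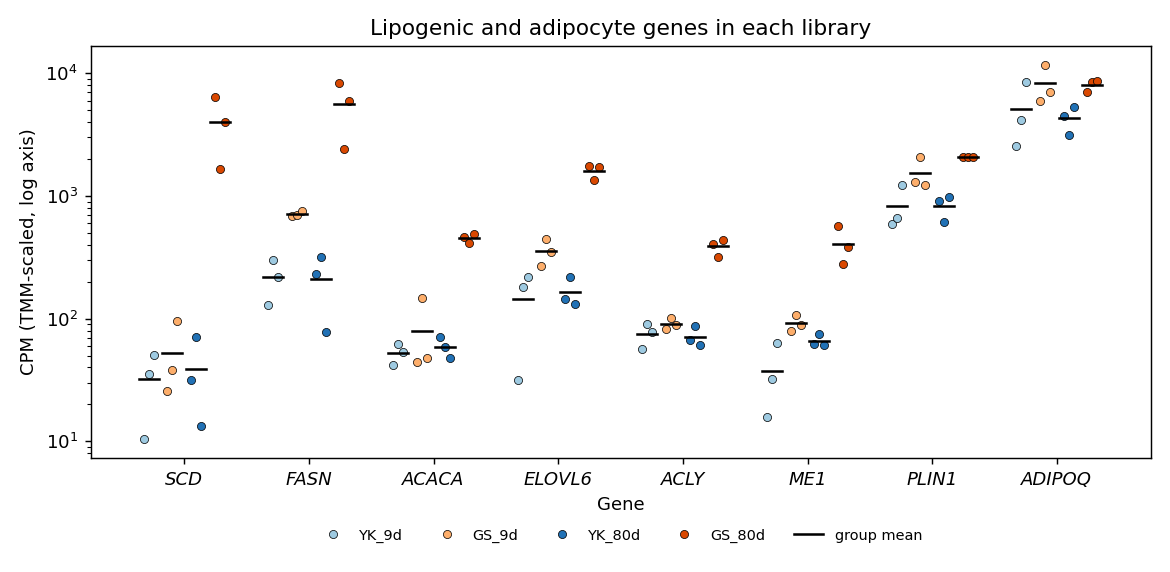
CPM of 8 genes of lipid synthesis and adipocyte identity in each library on a log axis, with bars at the group means. SCD averaged 4023 CPM in GS_80d and 32.1 to 52.8 CPM in the other groups.

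Some chaperone genes were lower in GS_80d than in YK_80d. HSP70.2, an inducible heat shock protein, stood at 82.7 ± 24.2 CPM in GS and 3012 ± 1227 in YK (-5.19 ± 0.37, adjusted p = 5.23e-05), and DNAJB1, its partner, at 102 ± 19.2 against 1487 ± 340 CPM (-3.86 ± 0.28, adjusted p = 5.23e-05). Both kept the call in every fit that left out 1 library. All 3 YK libraries lay above all 3 GS libraries, and 928 of the 944 genes that passed likewise had groups that did not overlap. HSP70.2 overlaps HSPA1L and has near-identical copies, so its own share of the reads is uncertain. Of 18 heat shock genes 4 were lower, DNAJB1, HSPA8 (-1.83 ± 0.31), HSPB1 (-1.59 ± 0.30) and HSPH1 (-2.47 ± 0.53), and 6 when adjusted over the list alone, with adjusted p = 1.98e-05 by the preset correlation and adjusted p = 0.451 with an estimated correlation. Without GS_80d replicate 1 the 4 became 2, since HSPB1 and HSPH1 had adjusted p = 0.0625 and 0.101, and HSPH1 also lost its call without GS_80d replicate 2 (0.0868).

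Some T and NK cell, ribosomal and cell cycle genes were lower in GS_80d, and T cell transcripts stood highest in YK_80d replicates 2 and 3. Of 25 T and NK cell genes 8 were lower, among them GNLY, a cytotoxic granule protein (-3.82 ± 0.60, adjusted p = 0.00614), and CCL5, a chemokine (-3.37 ± 0.76, 0.0293), and 14 were lower when adjusted over the list alone, with adjusted p = 0.602 with an estimated correlation. The 8 became 11 without YK_80d replicate 1, 3 without YK_80d replicate 2, and 1 without YK_80d replicate 3 or any of the GS_80d libraries. GNLY kept its call in these fits, and CCL5 lost it without YK_80d replicate 3 or any GS_80d library (adjusted p up to 0.127). Without YK_80d replicates 2 and 3 together none of the list passed by edgeR, with log2 differences of -2.49 for GNLY (adjusted p = 0.0835) and -0.41 for CCL5 (0.717). All 44 cytosolic ribosomal protein genes had negative differences with a median of -1.06, of which 14 passed, and 37 when adjusted over the list alone, with adjusted p = 0.602 with an estimated correlation. These genes belong to families with many copies, and RPS21 (-1.38 ± 0.31, adjusted p = 0.0253) and RPL35 (-1.31 ± 0.30, 0.0276) were examples. The 14 became 3 without YK_80d replicate 1, 19 without YK_80d replicate 2, and 0 without YK_80d replicate 3 or any GS_80d library. Of 42 cell cycle genes 3 were lower, among them TYMS, thymidylate synthase (-2.40 ± 0.58, adjusted p = 0.0320), and 19 lower and 1 higher when adjusted over the list alone, with adjusted p = 0.602 with an estimated correlation. The list stood at -1.20 in YK_80d replicate 1, below all 3 GS_80d libraries, and at 1.43 and 1.08 in replicates 2 and 3. The 3 became 22 without YK_80d replicate 1, 1 without GS_80d replicate 2 or 3, and 0 in the other fits. TYMS lost the call in 5 of 6 fits without 1 library (adjusted p up to 0.132), and without YK_80d replicates 2 and 3 the list's median turned from -1.54 to 0.42.

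Among single genes at 80 d, KIT was again lower in GS (-3.13 ± 0.34, adjusted p = 0.000962) and TSHR higher (3.30 ± 0.41, 0.00190). CLDN4, a tight junction protein of epithelia, stood at 1.48 ± 0.658 CPM in GS and 276 ± 243 in YK (-7.53 ± 1.14, adjusted p = 0.00686). The list of mammary and other epithelium, which holds CLDN4, stood at 1.80, 0.33 and -0.60 in YK_80d replicates 1, 2 and 3. In GS_80d it stood at -0.29, -1.17 and -2.32. Whether epithelium in the samples accounts for the CLDN4 result was not tested. MARCO, a scavenger receptor of macrophages, was at least 101-fold lower in GS_80d, where all 3 libraries were at 0. GRB10, an imprinted inhibitor of growth factor signalling, was lower by a log2 difference of -1.40 ± 0.20 (adjusted p = 0.00305). These 5 genes kept their calls whichever library was left out. In all, 944 genes passed, 489 higher and 455 lower in GS, 928 of them with groups that did not overlap, and the groups did not overlap for 31.4% of all genes, against 10% by chance. The count was 335 without YK_80d replicate 3, 255 without GS_80d replicate 1, 359 without GS_80d replicate 2 and 339 without GS_80d replicate 3. It was 290 without the libraries with muscle transcripts and 242 without YK_80d replicates 2 and 3.

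Between 9 d and 80 d in YK, some chaperone and immediate early genes rose. HSP70.2 rose from 70.3 ± 13.5 to 3012 ± 1227 CPM (log2 5.42 ± 0.38, adjusted p = 3.40e-05), DNAJB1 from 90.6 ± 19.6 to 1487 ± 340 CPM (4.04 ± 0.28, 3.40e-05), and ATF3, a transcription factor induced by stress, from 13.4 ± 3.82 to 171 ± 76.1 CPM (3.67 ± 0.42, 0.00497). All 3 older libraries lay above all 3 younger ones, and these calls held whichever library was left out. The groups did not overlap for 184 of the 186 genes that passed in YK, so the first point adds little. Of 18 heat shock genes 4 rose, and 6 when adjusted over the list alone, with adjusted p = 0.0636 with an estimated correlation. Of 22 immediate early genes 4 rose, among them JUN (2.53 ± 0.51, adjusted p = 0.0385), and 17 when adjusted over the list alone, with a median of 1.87 and adjusted p = 0.0636 with an estimated correlation. The heat shock calls fell to 1 without YK_9d replicate 1 and to 2 without YK_9d replicate 2, YK_80d replicate 1 or YK_80d replicate 2, and the immediate early calls to 2 without YK_80d replicate 3 and to 1 without any other of the 6 libraries. JUN lost its call in all 6 of these fits (adjusted p up to 0.123).

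Some T and NK cell genes rose with age in YK, and the older libraries with the most of these transcripts were YK_80d replicates 2 and 3. CD3E, a subunit of the T cell receptor complex, rose from 0.952 ± 0.442 to 21.0 ± 14.5 CPM (4.46 ± 0.72, adjusted p = 0.0244), with 4.24 CPM in YK_80d replicate 1, 29.5 in replicate 2 and 29.2 in replicate 3. CD8A rose by 5.10 ± 0.99 (adjusted p = 0.0376) and CCL5 by 3.94 ± 0.78 (0.0412). Of 25 list members 12 rose, and 20 when adjusted over the list alone, with a median of 3.51 (3.34 with 1 member at the floor) and adjusted p = 0.128 with an estimated correlation. The 12 became 0 without YK_9d replicate 1, YK_9d replicate 2 or YK_80d replicate 3, 1 without YK_9d replicate 3 or YK_80d replicate 2, and 15 without YK_80d replicate 1. CD3E, CD8A and CCL5 lost their calls in all of these fits except the last (adjusted p up to 0.0802, 0.138 and 0.144). Of 31 interferon response genes 1 rose, IRF1 (1.66 ± 0.33, adjusted p = 0.0374), and 27 when adjusted over the list alone, with adjusted p = 0.153 with an estimated correlation. IRF1 kept its call only without YK_80d replicate 1 (up to 0.102 otherwise).

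Some matrix, resident macrophage and red cell genes fell with age in YK. MMP2, a matrix metalloproteinase, fell from 1893 ± 214 to 681 ± 77.1 CPM (-1.48 ± 0.22, adjusted p = 0.0151), and POSTN, periostin, by a log2 change of -1.53 ± 0.31 (0.0403). Of 45 extracellular matrix genes 4 fell, and 21 when adjusted over the list alone, with adjusted p = 1.02e-13 by the preset correlation and adjusted p = 0.182 with an estimated correlation. Of 26 macrophage genes 4 fell and 1 rose. CD163, a scavenger receptor of resident macrophages, fell from 132 ± 16.5 to 30.8 ± 11.1 CPM (-2.09 ± 0.36, adjusted p = 0.0244), MRC1 fell (-2.52 ± 0.48, 0.0345), and CD86, a costimulator, rose (2.45 ± 0.48, 0.0345). Adjusted over the list alone 7 fell and 4 rose, with adjusted p = 0.495 with an estimated correlation. HBB, beta globin, fell from 1061 ± 542 to 175 ± 121 CPM (-2.60 ± 0.46, adjusted p = 0.0260), and 2 of 6 erythroid genes fell, also when adjusted over the list alone, with adjusted p = 0.0636 with an estimated correlation. PTN, pleiotrophin, fell by a log2 change of -2.64 ± 0.35 (adjusted p = 0.00766) and TEK, an angiopoietin receptor, rose (1.76 ± 0.25, 0.00960).

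Of these genes PTN and TEK kept their calls whichever library was left out, and MMP2 lost its call without YK_80d replicate 3 (-1.36, adjusted p = 0.0538). POSTN, CD163, MRC1, CD86 and HBB lost theirs in 4 to 6 of the 6 fits (adjusted p up to 0.123). The 4 matrix calls were 0 without YK_80d replicate 3, 1 without YK_9d replicate 1, 2 without YK_9d replicate 3 or YK_80d replicate 1, and 7 without YK_80d replicate 2. The 4 macrophage decreases were 2 without YK_80d replicate 1, 3 without YK_80d replicate 2 and 0 in the other fits, and the 2 erythroid calls were 1 without YK_80d replicate 1, 2 without YK_80d replicate 3 and 0 in the others. The skin list had a median of -4.60 for age in YK (-4.26 with 6 members at the floor), and 1 of 18 members passed, KRT71, which was at least 103-fold lower, a call lost in 5 of 6 fits without 1 library (adjusted p up to 0.117). Adjusted over the list alone 9 fell, with adjusted p = 0.128 with an estimated correlation. SCD (0.27 ± 0.74, adjusted p = 0.943), FASN (-0.05 ± 0.51, 0.990) and ACACA (0.17 ± 0.39, 0.927) did not pass in YK. In all, 186 genes passed, 125 higher and 61 lower at 80 d, with groups that did not overlap for 15.8% of all genes, against 10% by chance. The count was 33, 39 and 27 without YK_9d replicates 1, 2 and 3, and 51 and 39 without YK_80d replicates 2 and 3. It was 74 without YK_80d replicates 2 and 3 together, 14 without YK_9d replicates 2 and 3 together, and 51 without the libraries with muscle transcripts.

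**Figure D4:**
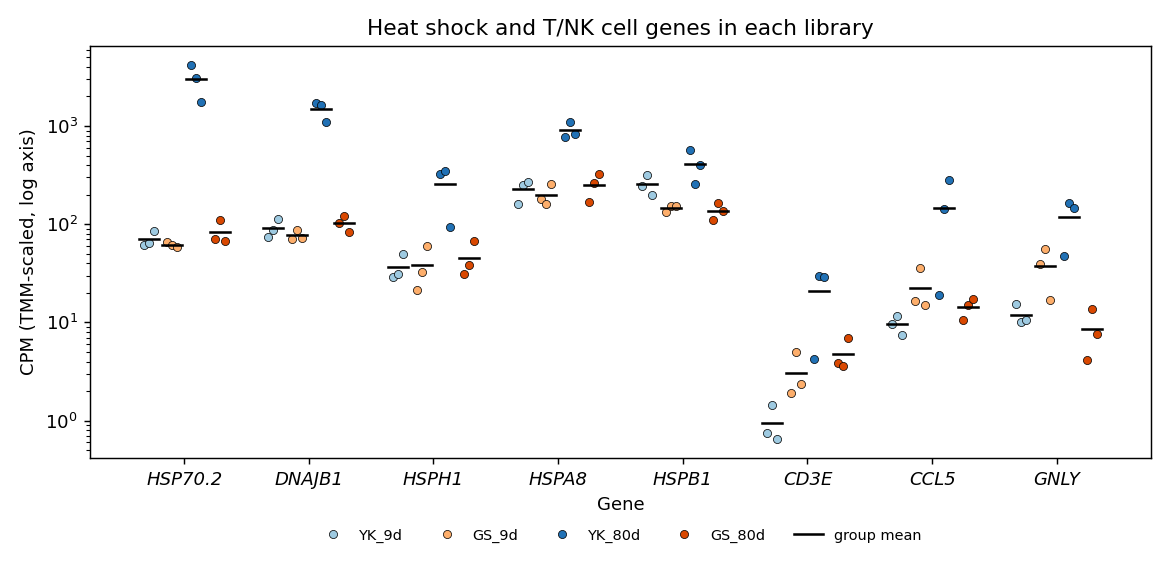
CPM of 5 chaperone genes and 3 T and NK cell genes in each library on a log axis, with bars at the group means. HSP70.2 averaged 3012 CPM in YK_80d and 62.1 to 82.7 CPM in the other groups.

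Between 9 d and 80 d in GS, some lipogenic genes rose. SCD rose from 52.8 ± 37.0 to 4023 ± 2375 CPM (log2 6.25 ± 0.93, adjusted p = 0.0117), ACLY from 90.6 ± 9.81 to 389 ± 63.6 CPM (2.10 ± 0.24, 0.00285), ACACA from 79.6 ± 58.3 to 456 ± 39.9 CPM (2.52 ± 0.41, 0.0126), and FASN from 711 ± 32.4 to 5588 ± 3016 CPM (2.97 ± 0.55, 0.0186). SLC2A5, the fructose transporter, rose by 3.70 ± 0.52 (adjusted p = 0.00843). All 3 older libraries lay above all 3 younger ones for these genes, but the groups did not overlap for any of the 409 genes that passed in GS. Of 21 lipogenesis genes 5 rose, and 12 when adjusted over the list alone, with adjusted p = 7.52e-13 by the preset correlation and adjusted p = 0.237 with an estimated correlation. ACLY, ACACA and SLC2A5 kept their calls whichever library was left out. SCD lost its call without GS_9d replicate 1 or 2 (adjusted p = 0.0506 and 0.0505), and FASN kept its own only without GS_80d replicate 2 (up to 0.0753 otherwise). The 5 calls were 2 without GS_9d replicate 1 or 2 and 3 without GS_9d replicate 3, GS_80d replicate 1 or GS_80d replicate 3.

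Several single genes fell with age in GS, while some immediate early genes rose. IGF2BP3, an RNA-binding protein of fetal tissues, fell from 9.42 ± 1.61 to 1.88 ± 0.435 CPM (-2.32 ± 0.34, adjusted p = 0.00868), PTK7, a receptor of Wnt signalling, from 23.5 ± 2.02 to 3.75 ± 0.325 CPM (-2.64 ± 0.26, 0.00249), and LSAMP, a cell adhesion protein, from 19.02 ± 2.61 to 1.47 ± 0.294 CPM (-3.69 ± 0.38, 0.00249). Of 11 imprinted growth genes 3 fell, MEST (-1.94 ± 0.25, adjusted p = 0.00742), GRB10 (-0.83 ± 0.19, 0.0435) and DLK1, a marker of preadipocytes, which was at least 176-fold lower at 80 d (0.0381; all 3 libraries at 0). Adjusted over the list alone 4 fell, with adjusted p = 0.330 with an estimated correlation. Of 26 adipose progenitor and stromal genes 3 fell (0 or 1 when 1 library was left out), and 4 fell and 1 rose when adjusted over the list alone, with a median of 0.01, a test direction downward and adjusted p = 0.983 with an estimated correlation. Of 22 immediate early genes 5 rose, among them the nuclear receptors NR4A1 (4.21 ± 0.63, adjusted p = 0.0108) and NR4A2 (2.23 ± 0.31, 0.00843), and 12 when adjusted over the list alone, with a median of 1.50 and adjusted p = 0.237 with an estimated correlation. IGF2BP3, PTK7, LSAMP, MEST, NR4A1 and NR4A2 kept their calls whichever library was left out, and GRB10 and DLK1 kept theirs in 0 of the 6 fits (adjusted p up to 0.167 and 0.116). The 3 imprinted calls were thus 1, and the 5 immediate early calls 3 without GS_9d replicate 1, GS_80d replicate 1 or GS_80d replicate 2.

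Some macrophage genes also fell in GS. Of 26 members 5 fell and 1 rose, and 14 fell and 1 rose when adjusted over the list alone, with adjusted p = 0.408 with an estimated correlation. MARCO was at least 109-fold lower at 80 d, CD163 fell (-1.85 ± 0.35, adjusted p = 0.0201) and C1QA, a complement component, fell (-1.94 ± 0.43, 0.0381). MARCO kept its call whichever library was left out, and CD163 and C1QA lost theirs in 5 and 6 of the 6 fits (adjusted p up to 0.0961 and 0.152), so that the 5 became 3 without GS_80d replicate 3, 2 without GS_9d replicate 3 and 1 in the other fits. All 44 ribosomal protein genes had negative values with a median of -0.93, of which 1 passed, RPL28 (-1.13 ± 0.26, adjusted p = 0.0427, lost in 6 of the 6 fits), and 36 when adjusted over the list alone, with adjusted p = 0.709 with an estimated correlation. Skeletal muscle genes had a median of -8.89 (-7.87 with 5 members at the floor), GS_9d replicate 3 holding most of these transcripts, and none of the 25 passed. In all, 409 genes passed, 213 higher and 196 lower at 80 d (273 and 144 when scaled by library size only), with groups that did not overlap for 33.7% of all genes, against 10% by chance. The count was 78, 108 and 122 without GS_9d replicates 1, 2 and 3, and 88, 83 and 82 without GS_80d replicates 1, 2 and 3. It was 150 without the libraries with muscle transcripts and 55 with the muscle score as a covariate.

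The interaction asks whether the change with age differed between the breeds. HSP70.2 (-5.01 ± 0.47, adjusted p = 0.00188) and DNAJB1 (-3.62 ± 0.36, 0.00217) differed between the breeds in their change with age, which passed in YK only, and both kept the call in each of the 12 fits that left out 1 library. CLMP, an adhesion molecule that has been tied to adipocyte differentiation, averaged 111 and 54.7 CPM in YK and 94.3 and 288 CPM in GS at 9 d and 80 d (2.64 ± 0.32, adjusted p = 0.00956), and kept its call as well. ACLY rose in GS (2.10 ± 0.24) and did not pass in YK (-0.07 ± 0.23), an interaction of 2.17 ± 0.32 (adjusted p = 0.0410), but this lost its call in 8 of the 12 fits (up to 0.140). SCD (5.98 ± 1.13, adjusted p = 0.113), FASN (3.02 ± 0.74, 0.185) and ACACA (2.35 ± 0.55, 0.180) did not pass, so their change with age was not shown to differ between the breeds. Of 15425 genes 10 passed, 3 with higher and 7 with lower values (6 and 4 when scaled by library size only), and 1693 had an unadjusted p under 0.05. The count was 90 without YK_80d replicate 1, 46 without GS_9d replicate 3, 6 without GS_9d replicate 2, GS_80d replicate 2 or GS_80d replicate 3, and 5 without YK_9d replicate 2, GS_9d replicate 1, YK_80d replicate 3 or GS_80d replicate 1.

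Genes with a breed difference at 9 d largely kept its direction at 80 d. Among the 157 genes that passed at 9 d, 142 (90.4%) had the same sign at 80 d, and among the 944 at 80 d, 784 (83.1%) had the same sign at 9 d. At both ages 65 genes were higher in GS, against 3.20 for independent lists, and 19 were lower, against 1.65, while 1 gene passed in opposite directions. KIT, TSHR, CIDEC and DGAT2 were among the genes called the same way at both ages. The 84 genes called the same way were 4 without YK_9d replicate 2, 21 without YK_9d replicate 1, 14, 25 and 50 without GS_9d replicates 2, 1 and 3, and 55 without GS_80d replicate 3. Across genes, which are not independent replicates, the log2 differences at the ages correlated with a Pearson r of 0.20 and a Spearman rho of 0.28.

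The age differences of the breeds shared 15 genes that rose, against 1.73 for independent lists, and 26 that fell, against 0.775, while 1 gene changed in opposite directions. ATF3, NR4A2 and IL6 rose in both breeds, and CD163, MMP2, FBN2 and MFAP5 fell in both. Most of these calls did not hold when 1 library was left out: of 6 fits, those kept in YK and GS were 6 and 3 for ATF3, 1 and 6 for NR4A2, 0 and 1 for IL6, 2 and 1 for CD163, 5 and 1 for MMP2, 4 and 1 for FBN2, and 0 and 1 for MFAP5. Of the 186 genes that passed in YK 140 (75.3%) had the same sign in GS, and of the 409 in GS 348 (85.1%) had the same sign in YK. The 41 genes called the same way were 7 to 24 when 1 library was left out, the lowest without YK_9d replicate 1 or YK_9d replicate 3. Across genes the Pearson r was 0.12 and the Spearman rho 0.23.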

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

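The interaction test, the gene list tests and their alternatives were fixed before the data were examined. So were the scaling by library size only and the fits leaving out each library in turn. Apart from these and the counts over other splits, the tests in this section were chosen only after the result they concern was seen. The use of library size scaling on the called lipogenic genes was also chosen then.

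Lipogenic genes were higher in GS_80d than in YK_80d, 13 of the list being past the threshold with a median log2 difference of 2.28. Fewer adipocytes in the YK_80d samples could lower them. The whole lipogenesis list differed by 0.66 more than the adipocyte identity list (pooled SD 0.332, n = 3 per group, 95% interval -0.0885 to 1.42). On this measure the lowest GS_80d library (0.352) lay above the highest YK_80d library (0.188). The interval reaches below 0, however, which leaves the share of adipocytes open. Muscle in a YK_80d library, or the scaling, could also shift the lipogenic genes. Their median was 2.24 without the libraries with muscle transcripts (10 of 13 past the threshold) and 2.33 with library size only (13 of 13). A breed difference in lipogenesis may also contribute, since GS is known as a fat breed, and so might feeding before sampling, which the data cannot separate. Adipocytes isolated from pigs matched for feed and fasting time would tell these apart.

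Some heat shock genes were higher in YK_80d than in GS_80d. Reads shared between near-identical HSP70 copies could inflate HSP70.2, but 4 genes of the heat shock list, which does not hold HSP70.2, passed, and although HSPA8 is of the HSP70 family, DNAJB1 and HSPB1 encode other chaperone families. Immune cells in YK_80d replicates 2 and 3 might carry these transcripts, yet the called genes stood higher in replicate 1, by a median of 0.554 log2 units, although this is a single library and cannot settle it. Stress or handling of the YK_80d pigs or samples could raise both groups of stress genes. Immediate early genes did have a median age change of 1.87 in YK, but it was 1.50 in GS, where HSP70.2 averaged 82.7 CPM at 80 d. Between the breeds at 80 d, 1 immediate early gene was higher and 3 were lower in GS. The list stood at 1.78, 0.97 and 0.86 in YK_80d replicates 1, 2 and 3. In GS_80d it stood at 0.59, 1.24 and -0.11, so the groups overlapped and stress or handling is left open. Sampling order and the time from slaughter to freezing, not given in the sources used here, would be needed.

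Of 25 T and NK cell genes 12 were higher in YK_80d than in YK_9d, mostly in replicates 2 and 3. Blood left in the samples could carry them, although HBB fell by a log2 change of -2.60 between the ages. Within YK_80d, however, the erythroid list stood at -2.46, -0.63 and -0.38 in replicates 1, 2 and 3. The T and NK cell genes were lowest in replicate 1 as well, so blood is left open. Lymph node tissue in the samples may be the source, and the B and plasma cell list had a median of 1.21, though 0 of its members passed, so the data cannot tell. Infiltration of the fat by T cells is also possible, and staining of sections would separate these.

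The age change differed between the breeds for 10 genes by the interaction test: HSP70.2 (-5.01), DNAJB1 (-3.62), CLMP (2.64), LBR (2.42), RASD1 (-3.46), ACLY (2.17), GNLY (-5.45), EPSTI1 (-6.09), RGS2 (-2.26) and MARCO (fitted -12.12, which is no bound because GS_80d was at 0). LBR lost its call in 6 of 12 fits without 1 library, RASD1 in 7, and GNLY, EPSTI1 and RGS2 in 10 each.

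By the preset correlation 15 lists had an interaction, and with an estimated correlation 0 of 40 did (lowest adjusted p = 0.199; 7 at an unadjusted p under 0.05; fry 0). Their medians were -2.91 for interferon response, -3.63 for T and NK cells (-3.49 at the floor), -1.04 for ribosomal proteins, 0.78 for lipogenesis, -1.49 for cell cycle, -0.61 for heat shock, -1.71 for SLA class II, -11.63 for skeletal muscle (-10.05 at the floor) and -0.36 for oxidative phosphorylation. Those of the others were 1.97 for erythroid, 0.40 for extracellular matrix, 0.21 for thyroid, retinoid and steroid hormone (0.14 at the floor), -0.21 for macrophages, -0.72 for Schwann cells and 4.85 for skin. Cell cycle and macrophage medians turned to 0.58 and 0.41 without YK_80d replicates 2 and 3.

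The counts were compared with those of other splits of the same samples. For genes, 1 of 10 splits, the real one, had as many as the real grouping in each pairwise comparison, and the highest other count was 1 at 9 d, 0 at 80 d, 2 in YK and 1 in GS, but 10 splits are too few for a share under 0.05. For the interaction 3 of 100 splits, the real one among them, had at least the 10 genes. The other splits exchange labels across breeds and ages, so breed and age differences enter their spread and can lower their counts. The share of splits is therefore no test of the interaction. The other splits that reached 10 genes had 42 and 1494, and each kept the GS_80d libraries together, which points to a structure of the samples. A further split that kept these libraries together had 0. For lists by the preset correlation, 5 of 10 splits had as many at 9 d (highest other 19), 3 at 80 d (14), 4 in YK (16) and 4 in GS (15), and 25 of 100 for the interaction (22), so the list counts do not exceed those of other groupings.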

How the results depend on the processing

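Counts of genes past the threshold are given in the order breed at 9 d, breed at 80 d, age in YK, age in GS, interaction, against 157, 944, 186, 409 and 10, and those called the same way in both as breed 84 and age 41. With library size only, age in YK gave 117 and the age overlap 21; the share of higher calls was 65.5% for age in GS against 52.1%, and 6 of 10 calls against 3 of 10 for the interaction, and the median of all genes in GS shifted to 0.134. DESeq2 gave 922, 2277, 896, 1530 and 392, overlaps 385 and 224. Limma-voom gave 359 at 9 d, 12 for age in YK and 1608 in GS, overlaps 181 and 5. The test against a 1.5-fold change gave 14, 198, 40, 47 and 4, overlaps 9 and 1, as a stricter test must. The 6 libraries alone gave 29 at 9 d, 46 and 1055 for age in YK and GS, overlaps 10 and 7, and a threshold of 0.01 gave overlaps 7 and 1. The cause was not tested for these.

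Leaving out 1 library gave 5 to 284, 255 to 916, 27 to 245, 78 to 122 and 5 to 90 genes, 8 to 13, 12 to 18, 14 to 17, 9 to 12 and 12 to 18 lists, and overlaps of 4 to 115 and 7 to 24. Fewer samples alone lower counts; the cause of the higher ones was not tested. No called gene changed sign. In the pairwise comparisons this was nearly fixed in advance, since the groups did not overlap for 157, 928, 184 and 409 of the called genes. Of 218 named calls 59 were kept in all fits without 1 library and 31 in every alternative. The interferon median for age in GS ran from -1.59 to 0.0919, the latter without GS_9d replicate 1. The median of the skeletal muscle list, breed difference at 80 d, ran from -9.45 to 0, and that of the skeletal muscle list, age difference in YK, from -5.32 to 7.84, turning without YK_80d replicate 3, which holds the transcripts.

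A replicate block, taking equal replicate numbers as pairs, gave 49 genes at 9 d, 65 for age in YK and 2 for the interaction, overlaps 31 and 16. The labels do not say that equal numbers are paired, and only 3 of 18 such pairs had a deviation correlation above 0.1, so the lower counts may come from degrees of freedom spent on the block.

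The following were chosen after seeing the data, and in them a lone sample is assumed to vary like the other groups. Without the 3 libraries with muscle transcripts there were 39, 290, 51 and 150 genes (interaction within 1.5-fold), overlaps 16 and 10; medians turned to 0.17 for muscle at 80 d, -0.30 and 0.0520 for oxidative phosphorylation in YK and the interaction, and -0.26 for ribosomal proteins in YK. With the muscle score as covariate there were 484 at 80 d and 55 for age in GS, age overlap 8, and muscle medians were -1.16, -0.0476, 0.43 and 0.68 (9 d, 80 d, GS, interaction). Without YK_80d replicates 2 and 3 there were 242 genes and 9 lists at 80 d, 74 genes in YK and 21 for the interaction, overlaps 33 and 7; medians turned for cell cycle (0.42 at 80 d, -1.50 in YK, 0.58 interaction), macrophages (0.38, 0.41 interaction) and muscle (0 at 80 d, -6.66 in YK). Without YK_9d replicates 2 and 3 there were 11 genes at 9 d, 14 genes and 22 lists in YK and 4 for the interaction, overlaps 6 and 5; medians in YK turned to 0.48 for adipocyte identity, 0.33 for fatty acid oxidation and 0.67 for mitochondrially encoded genes. Beyond the smaller number of samples, the cause was not tested.

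By the preset correlation 11, 14, 14, 11 and 15 lists passed. With an estimated correlation 0 did in each comparison, with 1, 3, 9, 4 and 7 at an unadjusted p under 0.05. In the same order fry gave 0, 3, 10, 5 and 0 in one direction, and 17, 26, 19, 26 and 13 in either direction.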

Other observations

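Some hormone and retinoid genes also differed between the breeds at 80 d. Of 22 thyroid, retinoid and steroid hormone genes 4 were higher in GS, among them ALDH1A1, a retinaldehyde dehydrogenase (188 ± 32.0 against 20.4 ± 1.65 CPM, log2 3.20 ± 0.43, adjusted p = 0.00265), and STAR, which moves cholesterol into mitochondria (3.16 ± 0.73, 0.0297). Adjusted over the list alone 6 were higher, with adjusted p = 0.153 with an estimated correlation, and the 4 were 1 or 2 when 1 library was left out. Of 22 cholesterol synthesis genes 3 were higher at 80 d, also when adjusted over the list alone, with a median of -0.06, a mean of 0.45, adjusted p = 0.127 by the preset correlation and adjusted p = 0.659 with an estimated correlation, so median and mean differ in sign. These 3 calls were 3 without GS_80d replicate 2, 1 without any other of the 6 libraries or without the libraries with muscle transcripts, and 0 without YK_80d replicates 2 and 3. KDM5D, a gene of the Y chromosome, was above 0 in all 12 libraries, and the labels give no sex.

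The tests of the KIT result were chosen only after it was seen. KIT was lower in GS at both ages, and mast cells express it, so fewer mast cells in the GS samples could be the cause. Of 4 other mast cell genes the closest to KIT, GATA2 at 9 d, still lay 2.44 log2 units above it, which speaks against this. KIT carries coat colour alleles with extra copies in white pigs, and such a genotype in YK may be an explanation, but genotypes were not analysed here.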
